A study of Xenopus tropicalis with 16 samples.

How the data were processed

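RNA was measured in livers of female Xenopus tropicalis by poly(A)-selected, stranded RNA sequencing. The 16 libraries fall into 4 groups of 4: unexposed, benzo[a]pyrene, triclosan and a mixture. Groups were taken from the sample labels, and replicates are named by the group and number in their titles. The labels call the samples biological replicates, so p-values here measure effects against the spread between such replicates. Doses, durations and the components of the mixture are not given in the sources used here.

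The deposited files hold, per the labels, gene-level FPKM (fragments normalised to transcript length and to library size) from Cufflinks, with a confidence interval and a status for each of 19921 Ensembl genes. Of these, 15674 carry a gene symbol, 4247 carry none, and 267 symbols are shared by more than 1 gene. The submitters named Trimmomatic 0.32.1, Bowtie 0.12.7, TopHat2 0.6, TopHat and Cufflinks 0.0.7 without giving the role or order of each. Loci are given on genome scaffolds, and the build is not given in the sources used here. A RefSeq-based table deposited beside the gene tables was not used. Read counts are not in the tables, so depth was read from the width of the Cufflinks confidence intervals, which implied 10.9 to 17.9 M fragments (M, mega) per library. No count of 0 could therefore be turned into a detection limit, and genes at 0 are described as listed at 0.

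Estimates whose status was not OK were treated as missing, which concerned 54 estimates of 10 genes. They were also left out of the shares of summed FPKM and of the implied fragments. Each library's FPKM were divided by a median-of-ratios factor computed over 3959 genes with FPKM of at least 1 in all 16 libraries. Genes with FPKM of at least 1 in at least 4 of the 16 libraries and at least 3 non-missing values per group were tested, which left 6918 genes. Values were analysed as log2(rescaled FPKM + 1). On this scale changes of genes near or below an FPKM of 1 are understated, so group means are given beside them.

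Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with the trend and robust options), all two-sided. One mean per group was fitted over all 16 libraries, leaving 12 residual degrees of freedom and a median of 3.3 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and genes below 0.05 were called. Each exposure was compared with unexposed, the mixture with each single exposure, and benzo[a]pyrene with triclosan. A further contrast compared the mixture with the sum of the single-exposure changes, and assumes that the mixture held both compounds. The procedure was tested on simulated data drawn from the means and spreads of the tested genes, with 196 genes changed in the benzo[a]pyrene libraries among 6761 tested. It called 150 of them and made 4 false calls, with 61.2% of 49 genes called at a simulated log2 change of 1 and 88% of 50 at a change of 2. The simulated noise was independent between genes, whereas real genes vary together, so these rates need not hold for the real libraries.

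Gene lists were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the 34 of 37 lists with at least 5 tested genes. The lists were repeated with camera and a correlation estimated per list, and with the fry rotation test from limma, which used statmod 1.5.0. List scores per library, the mean over the members of the log2 value minus the gene's mean over all libraries, were compared by exact permutation tests added after the lists had been seen. Most lists covered liver functions. They included AhR targets and pathway genes, xenobiotic enzymes, NRF2 targets, unfolded protein response, heat shock, p53 targets and gluconeogenesis. Insulin signalling, fatty acid synthesis and oxidation, cholesterol synthesis, bile acids, lipoproteins and amino acid catabolism were also covered. Others covered vitellogenesis, the thyroid axis, steroid and retinoid metabolism, acute phase proteins, interferon responses, cell cycle, the respiratory chain, ribosomal proteins, the proteasome, the circadian clock and extracellular matrix. Marker lists covered hepatocytes, erythroid cells, bile duct cells, macrophages, granulocytes, lymphocytes, endothelial cells, exocrine pancreas, fat and muscle, pigment cells, gallbladder or gut, and ovary.

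The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, called genes with a symbol were named if the groups did not overlap and a group mean reached an FPKM of 5, up to 12 highest and 12 lowest per exposure. Where fewer than 10 qualified, the genes with the smallest p were added up to 10 as values that did not pass. Up to 4 members per list were named, as were 26 genes chosen for the exposures, and up to 5 highest and 5 lowest called genes for the other comparisons. Genes named outside this rule are said to have been chosen after their values were seen.

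Shares of summed FPKM were compared between groups by exact permutation tests, in which 4 against 4 libraries can give no p below 0.029. Correlations of log2 changes between exposures were compared with 100 simulations in which the unexposed libraries alone linked the comparisons. Alternatives covered FPKM without rescaling, quantile normalization, pseudocounts of 0.1 and 5, other filters, the replicate number as a block and fits on only the groups compared. Library weights, limma without the robust option, failed estimates taken as listed, and each library left out in turn were also run. Fits without the libraries of high rRNA share, fits with rRNA and mitochondrial shares as covariates, and contrasts pooling groups by compound were added after the data had been seen. Tables were read with Python 3.11.15 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.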

Results

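Gene expression was measured in liver samples of female tropical clawed frogs (Xenopus tropicalis) that were unexposed or exposed to benzo[a]pyrene, triclosan or a mixture, with 4 biological replicates per group. Benzo[a]pyrene is a polycyclic aromatic hydrocarbon and a ligand of the aryl hydrocarbon receptor (AhR). Triclosan is a chlorinated antibacterial agent. The comparisons ask what exposure to endocrine disruptors, which the series title calls chronic, changed in the liver transcriptome, and whether the mixture differed from its presumed components. Each library gave values for 19921 genes, of which 12283 to 13379 were above 0 and 4832 to 6833 had an FPKM of at least 1. The confidence intervals of the deposited values implied 10.9 to 17.9 M fragments (M, mega) per library. Values below are rescaled FPKM, as mean ± SD over 4 libraries per group (n = 4), and changes are log2 differences of FPKM + 1 with their standard error (SE). The median SE over the 6918 genes tested was 0.24. As deposited, before rescaling, the median log2 change over genes was -0.157 for mixture minus unexposed and -0.133 for mixture minus benzo[a]pyrene.

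Transcripts of a few gene classes dominated every library. Shares leave out estimates whose status was not OK, among them the albumin gene alb in all 16 libraries and the globin hba1 in some. The mitochondrial gene COX1 is left out in benzo[a]pyrene replicates 3 and 4 and mixture replicate 4, and COX3 in benzo[a]pyrene and mixture replicates 4. The mitochondrial shares of those libraries therefore lack genes that the other libraries include. Ribosomal protein genes took 52.2 ± 5.08% of summed FPKM in unexposed livers and 47 ± 8.49% in mixture livers. Mitochondrial genes took 14.9 ± 3.69% in unexposed, 20.5 ± 7.26% in benzo[a]pyrene, 13.8 ± 3.26% in triclosan and 21.4 ± 5.76% in mixture livers. The exact permutation p for the mitochondrial share was 0.0857 for the mixture and 0.257 for benzo[a]pyrene, and no adjusted p over the 15 comparisons of shares was below 0.923. The 10 most abundant genes took 33.1 ± 5.34% in unexposed, 32.8 ± 6.11% in benzo[a]pyrene (exact p = 0.971), 32.2 ± 1.29% in triclosan (exact p = 0.8) and 36.3 ± 7.3% in mixture livers (exact p = 0.571). Without unexposed replicate 3, the triclosan difference was -3.41 percentage points (exact p = 0.0286). Ribosomal RNA, which poly(A) selection should remove, took 10.59% of mixture replicate 4 and 3.45% of benzo[a]pyrene replicate 4. These libraries also had the lowest median rank correlations with the others, 0.824 and 0.828, against 0.856 to 0.889 for the remaining libraries.

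**Figure D1:**
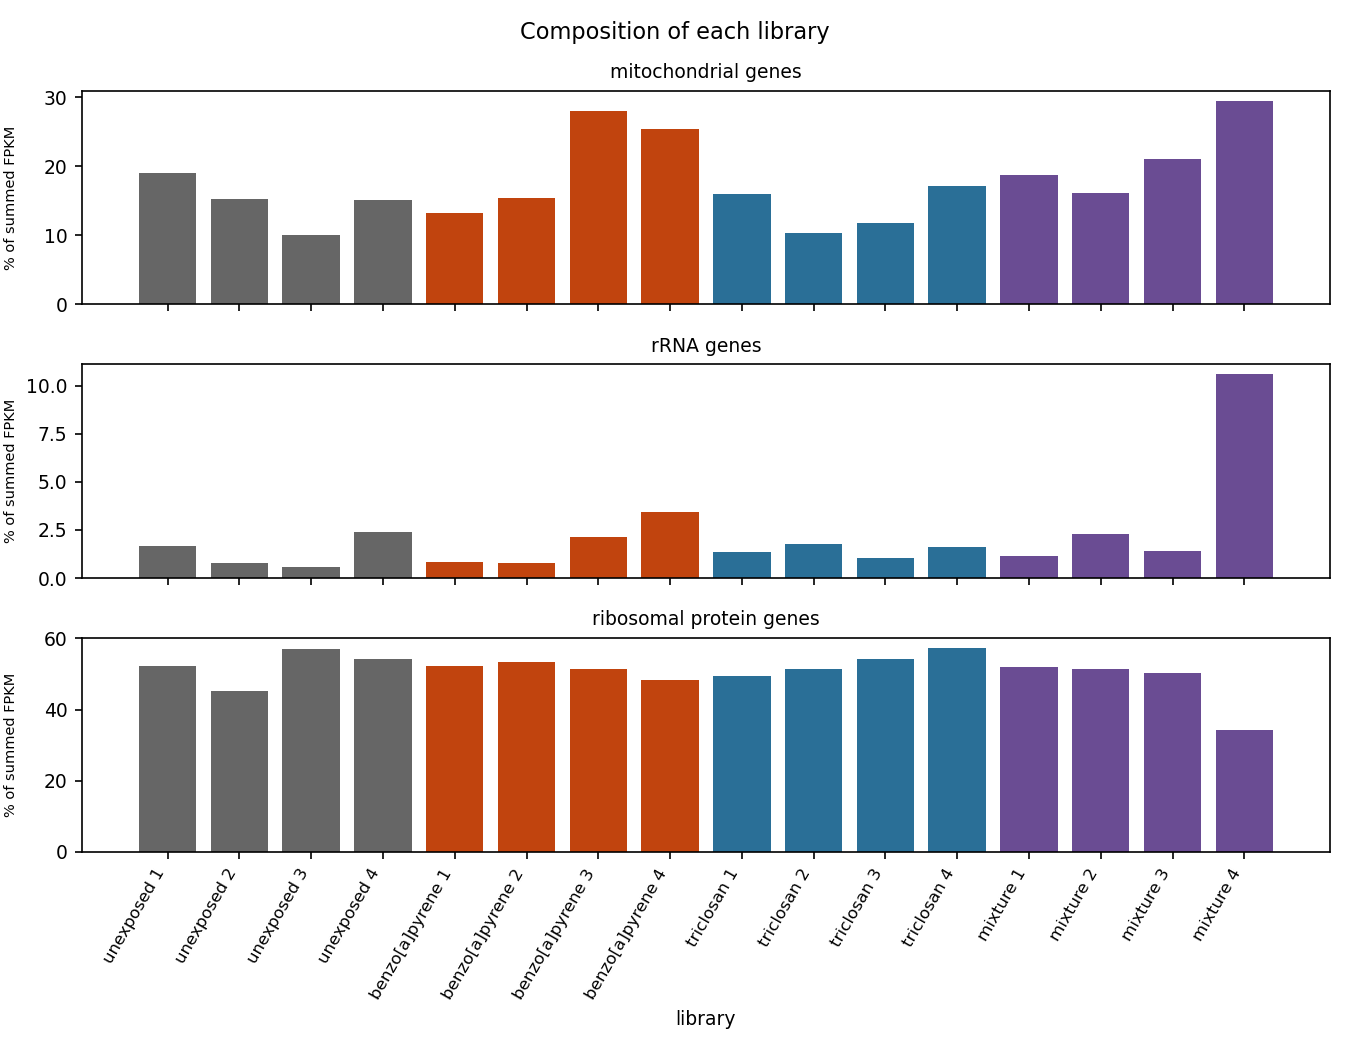
Share of summed FPKM (%, vertical axis) taken by mitochondrial, rRNA and ribosomal protein genes in each of the 16 libraries (horizontal axis), 1 bar per library coloured by group. Mixture replicate 4 had the highest rRNA share (10.59%) and the lowest ribosomal protein share (34.3%).

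Benzo[a]pyrene livers differed from unexposed livers in 2 genes past the test, both higher in all 4 exposed libraries than in any unexposed one. Transcripts of kdm6b (ENSXETG00000015636, scaffold GL173913.1, 55724 to 77743), which encodes a demethylase of the repressive histone mark H3K27me3, rose from 0.755 ± 0.177 to 3.23 ± 1.08 (log2 change 1.23, SE 0.19, limma adjusted p = 0.0344). XB-GENE-5857146 (ENSXETG00000011506, scaffold GL172651.1, 3194693 to 3200199), which has no descriptive symbol, rose from 1.41 ± 0.36 to 5.21 ± 0.799 (log2 change 1.37, SE 0.20, adjusted p = 0.0344). The 95% confidence intervals were 0.83 to 1.64 for kdm6b and 0.94 to 1.81 for XB-GENE-5857146. Both genes fall outside the naming rule and were chosen after their values were seen. Many more genes lay below an unadjusted p of 0.05, namely 1005 (586 higher and 419 lower) where 346 would come by chance. Other splits of the same libraries gave 1263, 1038 and 1031 such genes, so this excess cannot be assigned to exposure. The exposed and unexposed libraries did not overlap in 536 genes, or 7.7%, against 2.9% by chance.

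Genes with the next smallest p did not pass the test, with adjusted p from 0.0793 to 0.106. The prostaglandin-degrading enzyme hpgd (ENSXETG00000016904) stood at 5.22 ± 1.43 in unexposed and 20 ± 11.2 in benzo[a]pyrene livers. The pyrimidine nucleotidase nt5c3a, which is abundant in maturing red cells, stood at 2.96 ± 0.158 and 9.63 ± 2.8. Transthyretin (ttr, ENSXETG00000004725), a plasma carrier of thyroid hormone, stood at 377 ± 178 and 92.5 ± 52.9, a log2 difference of -2.05 (SE 0.39). The gene prodh2 stood at 15 ± 1.68 and 6 ± 2.24, and impdh2, the rate-limiting enzyme of guanine nucleotide synthesis, at 41.8 ± 4.81 and 19.8 ± 3.19. Transcripts of msl1 stood at 4.15 ± 0.679 and 11.8 ± 4.81. The other genes in this set were cenpk, susd1, ccdc69 and mllt10, with log2 differences of 0.79, 1.09, 0.76 and 0.76.

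**Figure D2:**
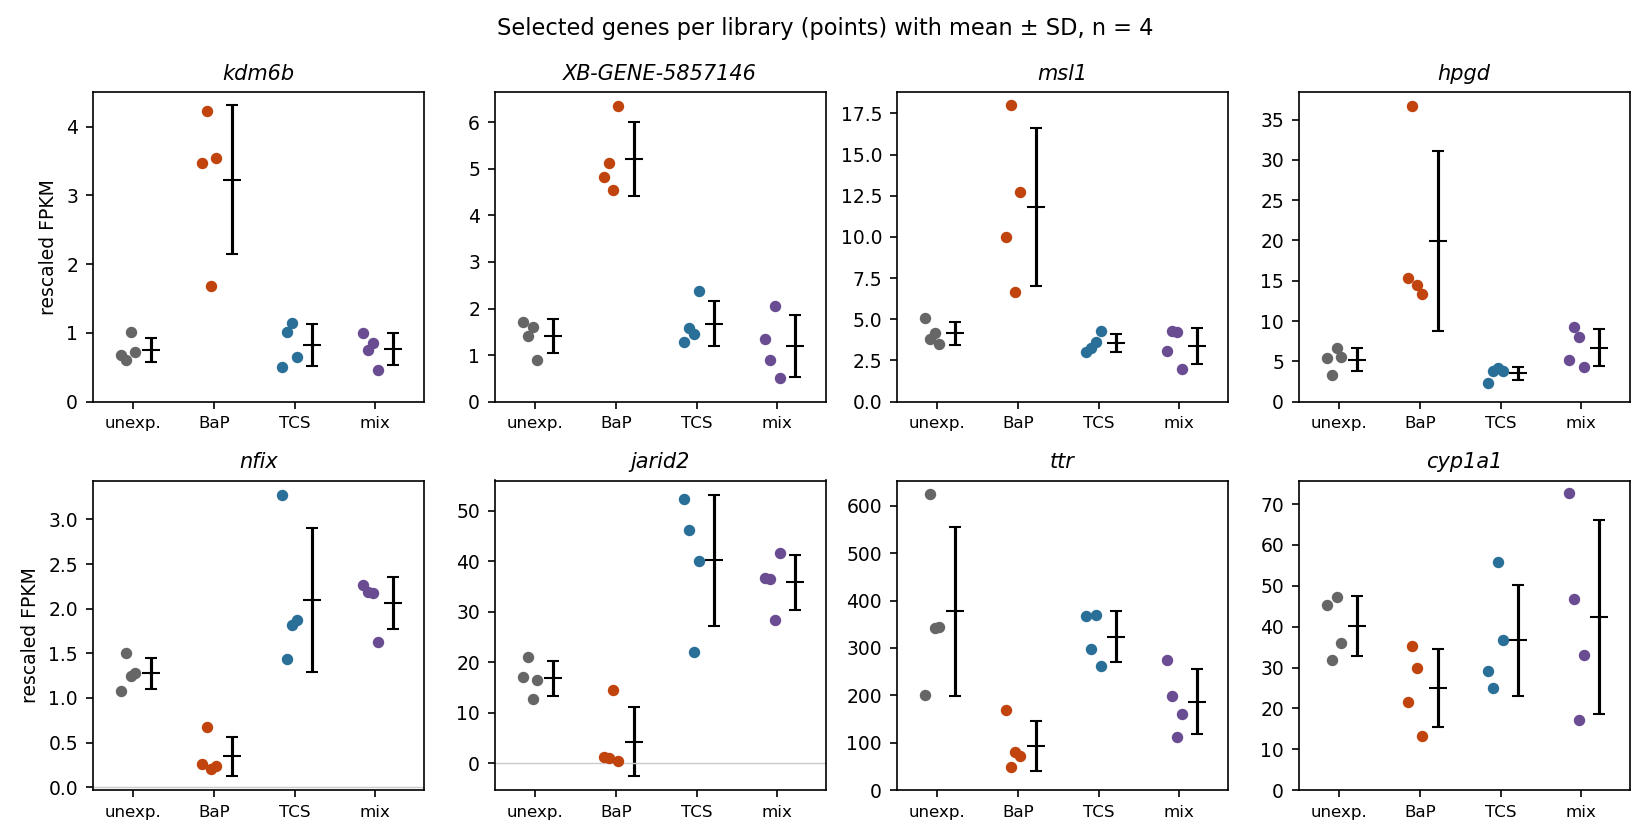
Rescaled FPKM (vertical axis) of 8 genes in unexposed (unexp.), benzo[a]pyrene (BaP), triclosan (TCS) and mixture (mix) livers (horizontal axis), with each library as a point and the mean ± SD (n = 4) beside it. Kdm6b and XB-GENE-5857146 were higher in all 4 benzo[a]pyrene libraries, and jarid2 averaged 4.33 in benzo[a]pyrene livers against 35.8 in mixture livers, while cyp1a1 overlapped between groups.

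Transcripts of red blood cells were shifted higher as a list in benzo[a]pyrene livers, clearly so in 3 of 4 libraries, and those of the hepatocyte secretory pathway and of hepatocytes were shifted lower. Of 16 erythroid markers, 15 lay above 0, with a median log2 change of 0.94 (camera adjusted p = 4.15e-08, and adjusted p = 0.32 with an estimated correlation). The mean score of this list was 0.78, 1.26 and 0.88 in benzo[a]pyrene replicates 1, 2 and 4 but -0.05 in replicate 3, close to the unexposed range of -0.51 to -0.11. Among the markers, the globin hbd stood at 145 ± 134 in unexposed and 947 ± 417 in benzo[a]pyrene livers, with 345 in unexposed replicate 1 (others 68.2 to 89.9) and 367 in benzo[a]pyrene replicate 3, and ank1, a red cell membrane skeleton gene, at 26.8 and 74.6. The list of unfolded protein response and ER chaperone genes had 28 of 29 members below 0 and a median of -0.88 (adjusted p = 1.2e-10, and adjusted p = 0.32 with an estimated correlation). The translocon subunit ssr4 stood at 338 ± 64.4 in unexposed and 157 ± 10 in benzo[a]pyrene livers, and the disulfide isomerase pdia3 at 61.8 and 19.8. The mean score of this list ranged from -0.97 to -0.32 in the benzo[a]pyrene libraries and from -0.50 to 1.22 in the unexposed ones, which overlapped (exact p = 0.114). Hepatocyte markers had 26 of 28 members below 0 and a median of -0.46 (adjusted p = 3.25e-06, and adjusted p = 0.32 with an estimated correlation). The hepatocyte transcription factor cebpa stood at 47.1 ± 6.88 in unexposed and 18.1 ± 7.92 in benzo[a]pyrene livers.

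Several metabolic and secreted-protein lists were also shifted lower in the benzo[a]pyrene group. Amino acid catabolism and acute phase scores did not fall library by library as the erythroid score rose. In replicates 1 to 4 the erythroid score was 0.78, 1.26, -0.05 and 0.88. In that order amino acid catabolism scored 0.27, -0.29, -0.52 and -0.16, and acute phase genes 0.03, -0.12, -0.48 and -0.70. Acute phase, coagulation and complement genes had a median of -0.51 with 44 of 48 below 0 (adjusted p = 9.34e-07, and adjusted p = 0.387 with an estimated correlation), and the complement gene c9 stood at 533 in unexposed and 303 in benzo[a]pyrene livers. Amino acid catabolism and urea cycle genes had a median of -0.37 (adjusted p = 0.000241), xenobiotic enzymes -0.26 (0.00695), fatty acid oxidation -0.29 (0.0123) and heat shock genes -0.19 (0.0172). With an estimated correlation, these 4 lists had an adjusted p = 0.387 as well. Among xenobiotic genes, the cytochrome P450 cyp2a13 stood at 6.9 ± 1.51 and 1.98 ± 0.879, and the glucuronosyltransferase ugt1a6 at 10.9 and 7.03. Bile acid and cholesterol disposal genes had a median of -0.44 (adjusted p = 0.000508) and bile duct markers of -0.64 with all 9 below 0 (adjusted p = 0.00335). These 2 lists had an adjusted p = 0.196 with an estimated correlation and passed the fry test, each with an adjusted p = 0.041. The bile acid conjugating enzyme baat stood at 20.3 and 12, and the biliary keratin krt19 at 326 and 211. Steroid and retinoid metabolism had a median of -0.37 with 20 of 21 below 0 (adjusted p = 0.00122, and adjusted p = 0.252 with an estimated correlation). Gluconeogenesis, glycolysis and glycogen genes had a median of -0.32 (adjusted p = 0.00379, and adjusted p = 0.32 with an estimated correlation).

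Ribosomal proteins (median -0.16, adjusted p = 0.000331) and the respiratory chain (median -0.18, adjusted p = 0.00176) were also shifted lower, and cell cycle genes were shifted higher (median 0.21, adjusted p = 0.00695). All 3 had an adjusted p = 0.458 with an estimated correlation. Among cell cycle genes, the DNA primase subunit prim1 stood at 2 in unexposed and 4.8 in benzo[a]pyrene livers. Lipoprotein genes had a median of -0.39 (adjusted p = 0.0243) and 6 granulocyte markers of -0.74 (adjusted p = 0.00995), and both had an adjusted p = 0.389 with an estimated correlation. The granulocyte receptor csf3r stood at 2.14 ± 0.322 and 0.831 ± 0.52. In all, 17 of 34 lists were called with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.196) and 2 by fry. No member of any list passed over all genes, while 26 of 790 members passed when adjusted over the list alone, among them 9 erythroid markers and 4 ER chaperone genes.

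The list of AhR targets and pathway genes did not pass the list test in benzo[a]pyrene livers (median -0.37 over 6 genes, adjusted p = 0.151). It mixes targets with other pathway genes, so it is not a test of target induction alone. Cyp1a1 (ENSXETG00000021140), a classic AhR target, stood at 40.1 ± 7.32 in unexposed, 25 ± 9.65 in benzo[a]pyrene, 36.7 ± 13.6 in triclosan and 42.4 ± 23.6 in mixture livers. The benzo[a]pyrene difference was -0.73 (SE 0.39, adjusted p = 0.391). Cyp1b1 was listed at 0 in all 16 libraries, and cyp1c1 and ahrr stayed at or below 0.316 and 0.141. The p53 and DNA damage list did not pass either (median 0.05, adjusted p = 0.151), although its members fas and XPC stood at 2.81 ± 0.306 and 2.3 in unexposed and 6.27 ± 2.15 and 6.05 in benzo[a]pyrene livers.

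The adjusted p of the remaining lists in benzo[a]pyrene livers was 0.0509 for lymphocyte markers (median 0.45), 0.0669 for fatty acid synthesis (-0.41), 0.0693 for NRF2 targets (-0.31) and 0.0802 for cholesterol synthesis (-0.33). The antioxidant enzyme prdx6, an NRF2 list member, stood at 92.1 ± 14.9 in unexposed and 44.3 ± 8.88 in benzo[a]pyrene livers. It was 0.0879 for both vitellogenesis (-0.28) and interferon genes (0.20), 0.161 for macrophages (-0.18), 0.233 for the circadian clock (0.21) and 0.309 for extracellular matrix (-0.06). It was 0.526 for insulin signalling (-0.09), whose member igfbp2 stood at 22 ± 7.03 and 6.55 ± 1.97. It was 0.704 for the proteasome (0.02), 0.749 for endothelial cells (-0.05) and 0.85 for fat and muscle (0.01). The thyroid axis had a median of 0.29 and a mean of 0.02, and exocrine pancreas markers a median of 0.38 and a mean of -0.04 with a test directed down, each with an adjusted p of 0.854. Pigment cell, gallbladder or gut, and ovary markers had 1, 4 and 2 tested genes and were not tested.

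The calls of kdm6b and XB-GENE-5857146 depended on settings and on single libraries. Without rescaling, with a pseudocount of 0.1 and with the replicate number as a block, the adjusted p was 0.183, 0.083 and 0.15 for XB-GENE-5857146 and 0.226, 0.083 and 0.15 for kdm6b. Leaving out unexposed replicates 1, 2, 3 or 4, or benzo[a]pyrene replicates 2 or 4, gave 0 called genes, while leaving out benzo[a]pyrene replicate 1 gave 3 and leaving out benzo[a]pyrene replicate 3 gave 46. Of the 17 list calls, 9 held in each of the 8 fits that left out 1 library: erythroid, hepatocyte and bile duct markers, ER chaperones, acute phase, amino acid catabolism, bile acid disposal, steroid and retinoid metabolism, and gluconeogenesis. Without unexposed replicate 1, the adjusted p was 0.127 for cell cycle, 0.0931 for ribosomal proteins, 0.0569 for heat shock and 0.0543 for lipoprotein genes. Without unexposed replicate 2, it was 0.0781 for fatty acid oxidation, 0.0814 for granulocytes and 0.102 for xenobiotic enzymes, and without unexposed replicate 3 it was 0.0946 for lipoproteins. Without benzo[a]pyrene replicate 1 it was 0.19 for ribosomal proteins, and without replicate 2 it was 0.0627 for granulocytes. Without benzo[a]pyrene replicate 3 it was 0.0829 for fatty acid oxidation and 0.181 for the respiratory chain, and without replicate 4 it was 0.0766 for cell cycle and 0.119 for lipoproteins.

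**Figure D3:**
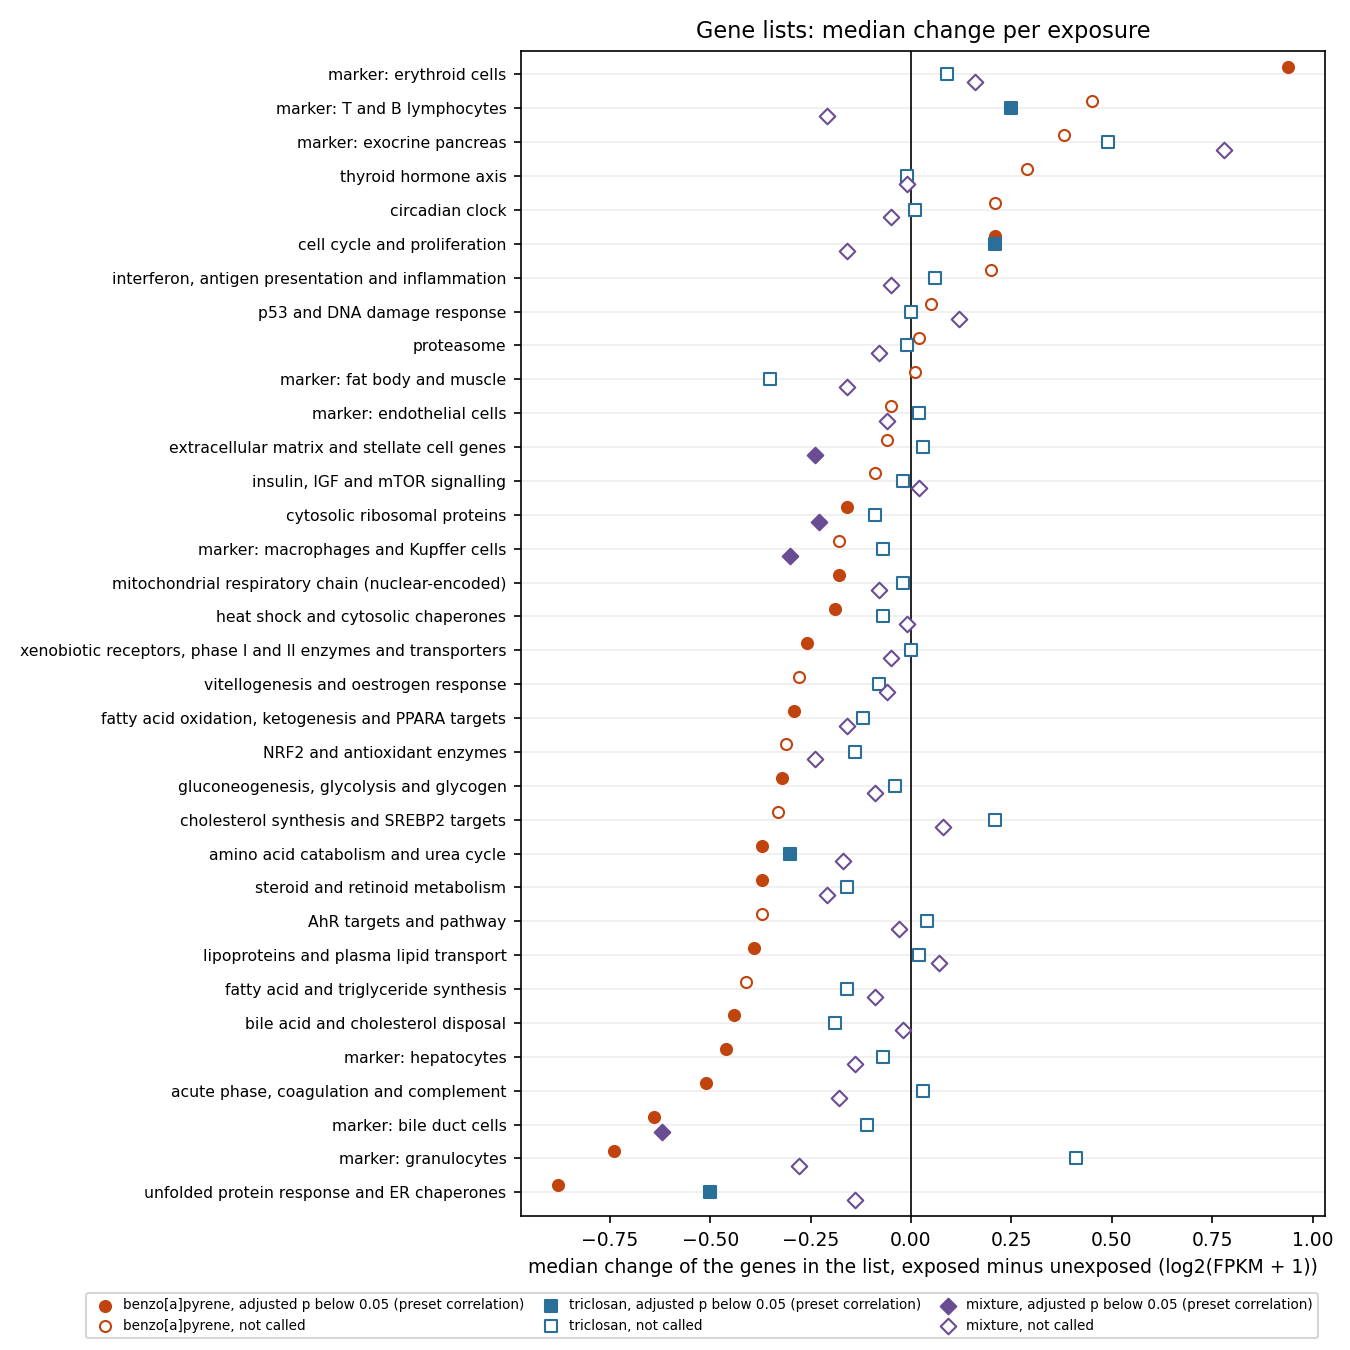
Median log2 change of the genes in each of 34 lists (vertical axis) for each exposure minus unexposed (horizontal axis, log2 of FPKM + 1), with filled symbols for lists called with a preset correlation. In benzo[a]pyrene livers 17 lists were called, from -0.88 for ER chaperones to 0.94 for erythroid markers, against 4 each in triclosan and mixture livers, and none of these was called with an estimated correlation.

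Triclosan livers had lower transcripts of ER chaperones and amino acid catabolism as lists, and higher cell cycle and lymphocyte transcripts, by a test with a preset correlation. All 4 lists had an adjusted p = 0.988 with an estimated correlation, and fry called none (smallest adjusted p = 0.994). ER chaperones had 24 of 29 members below 0 and a median of -0.50 (camera adjusted p = 2.02e-05, and adjusted p = 0.988 with an estimated correlation), with the ER stress factor manf at 7.79 ± 10.5 in unexposed and 0.494 ± 0.414 in triclosan livers. The unexposed libraries spread widely in this list, as given above, and the score difference had an exact p of 0.343. Cell cycle genes had a median of 0.21 (adjusted p = 0.0165), amino acid catabolism -0.30 (adjusted p = 0.0371) and lymphocyte markers 0.25 (adjusted p = 0.0371), each with an adjusted p = 0.988 with an estimated correlation. Triclosan replicate 3 stood apart in immune markers, with scores of 0.71 for lymphocytes (others -0.28 to 0.20), 2.14 for granulocytes (-0.20 to 0.43) and 0.98 for macrophages (-0.14 to 0.15). The adjusted p for lymphocytes was 0.328 without triclosan replicate 3, 0.153 without triclosan replicate 2, 0.248 without unexposed replicate 1 and 0.131 without unexposed replicate 3. For amino acid catabolism it was 0.279 without triclosan replicate 3, 0.0836 without triclosan replicate 1, 0.248 without unexposed replicate 1 and 0.687 without unexposed replicate 2. For cell cycle genes it was 0.549 without triclosan replicate 1, 0.418 without unexposed replicate 1 and 0.0502 without unexposed replicate 4. The glutaminase gls2 stood at 3.73 in unexposed and 1.56 in triclosan livers, and the T cell receptor subunit CD247 at 0.105 and 0.685. No list member passed when adjusted over the list alone. The smallest adjusted p among the other lists was 0.322, for steroid and retinoid metabolism (median -0.16). The list of AhR targets and pathway genes had a median of 0.04 (adjusted p = 0.86). Median, mean and test differed in sign for xenobiotic, insulin, lipoprotein, vitellogenesis, thyroid, extracellular matrix, macrophage and endothelial lists, with adjusted p from 0.808 to 0.995.

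No single gene passed the test in triclosan livers (limma, smallest adjusted p = 0.965), and 303 genes lay below an unadjusted p of 0.05 where 346 would come by chance. Groups did not overlap in 2.8% of genes, against 2.9% by chance. The glycerol 3-phosphate dehydrogenase gpd1 stood at 31.3 ± 2.65 in unexposed and 18 ± 3.24 in triclosan livers, the CpG-binding protein cxxc1 at 4.14 ± 0.873 and 8.3 ± 0.757, and the ubiquitin hydrolase uchl3 at 8.51 ± 1.04 and 4.88 ± 1.16. The other genes of smallest p were c14orf166 (log2 difference -1.02), cinp (-0.88), rnf149 (-0.53), sult6b1 (0.77), NFKBIZ (0.72) and dusp6 (-0.46), together with the small RNA Vault, listed at 0 in all triclosan and mixture libraries. CYP3A5 (ENSXETG00000033940), a drug-metabolising P450 of a family induced through the pregnane X receptor, stood at 7.14 ± 2.72 in unexposed, 18.6 ± 8.48 in triclosan and 23.1 ± 13.6 in mixture livers, and the adjusted p was 0.965 and 0.731. Xenobiotic enzymes as a list had a median of 0.00 and a mean of 0.02 with a test directed down (adjusted p = 0.939). Leaving out unexposed replicate 1 gave 1 called list, unexposed replicate 4 gave 7, and triclosan replicates 1 and 3 gave 2 each, while leaving out any library gave 0 called genes.

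Mixture livers had lower transcripts of ribosomal proteins, macrophages, extracellular matrix and bile ducts as lists, by a test with a preset correlation. None of the 4 was called with an estimated correlation (smallest adjusted p = 0.651). Ribosomal proteins had 61 of 74 members below 0 and a median of -0.23 (camera adjusted p = 3.76e-05, and adjusted p = 0.918 with an estimated correlation), and rpl36 stood at 8530 ± 1670 in unexposed and 5900 ± 1410 in mixture livers. Mixture replicate 4, the library with 10.59% rRNA, had the lowest ribosomal protein share. All 13 macrophage markers lay below 0, with a median of -0.30 (adjusted p = 0.00917, and adjusted p = 0.918 with an estimated correlation), and the lysosomal protease ctss stood at 21.2 ± 5.94 and 11.1 ± 3.81. Extracellular matrix genes had 19 of 20 members below 0 and a median of -0.24 (adjusted p = 0.0235, and adjusted p = 0.918 with an estimated correlation). Bile duct markers had a median of -0.62 with 8 of 9 below 0 (adjusted p = 0.0235, and adjusted p = 0.651 with an estimated correlation), and the tight junction gene cldn7 stood at 3.21 and 1.43. Fry called no list (smallest adjusted p = 0.504). Without unexposed replicate 1, the adjusted p was 0.124 for ribosomal proteins and 0.0895 for extracellular matrix, and without unexposed replicate 2 it was 0.265 for extracellular matrix and 0.192 for bile ducts. Without mixture replicate 3 it was 0.118 for extracellular matrix and 0.119 for bile ducts, and without mixture replicate 2 it was 0.0501 for bile ducts. When adjusted over the list alone, 2 of 790 members passed, the pancreatic genes SYCN (higher) and BHLHA15 (lower). Among the other lists, NRF2 targets had the smallest adjusted p (0.0624, median -0.24). The list of AhR targets and pathway genes had a median of -0.03 (adjusted p = 0.852). Median, mean and test differed in sign for AhR, xenobiotic, insulin, vitellogenesis, heat shock and circadian clock lists, with adjusted p from 0.852 to 0.856.

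No single gene passed the test in mixture livers (limma, smallest adjusted p = 0.731). Below an unadjusted p of 0.05 there were 454 genes (232 higher and 222 lower) where 346 would come by chance. Other splits of the same libraries gave up to 692. Groups did not overlap in 313 genes, or 4.5%, against 2.9% by chance. The genes of smallest p included the ERK phosphatase dusp6 (2.3 ± 0.171 in unexposed and 1.25 ± 0.172 in mixture livers), the Ras-ERK inhibitor spred1 (3.75 ± 0.359 and 1.69 ± 0.724) and the ETS factor etv1 (1.86 and 0.802). The transporter abcc5 stood at 9.52 ± 1.37 and 21.7 ± 7.69, the haem synthesis enzyme alad at 60.5 ± 13.9 and 30.8 ± 12.7, and the LIM protein fhl1 at 5.79 ± 1.56 and 2.45 ± 0.577. The others were dusp28 (log2 difference 0.71), bloc1s3 (0.91), rcan1 (-0.77) and the small nuclear RNA U1, listed at 0 in all unexposed libraries and at 5.98 ± 1.48 in mixture livers. Leaving out unexposed replicate 4 gave 10 called lists, mixture replicate 1 gave 7 and mixture replicate 3 gave 2, while leaving out any library gave 0 called genes.

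Metabolic and endocrine genes chosen for the exposures did not pass the test in any exposure. The glucose 6-phosphatase g6pc (ENSXETG00000013641), which releases glucose from the liver, stood at 7.18 ± 5.74 in unexposed, 11 ± 8.21 in benzo[a]pyrene, 18.7 ± 11.8 in triclosan and 20.6 ± 10.6 in mixture livers, with an adjusted p of 0.731 in the mixture. Its neighbour G6PC stood at 5.41 in unexposed and 32.9 ± 50.4 in benzo[a]pyrene livers, where replicate 4 had 108 and the others 4.16 to 14.4, and the gluconeogenic enzyme fbp1 at 100 ± 50.6 and 58 ± 24.5. The yolk precursor vtga2 stood at 1000 ± 1210, 1830 ± 1910, 2600 ± 1710 and 2610 ± 2250 in the same order of groups. The oestrogen receptor esr1 stood at 1.65 ± 0.412 in unexposed and 1.03 ± 0.281 in benzo[a]pyrene livers. Means in unexposed and in benzo[a]pyrene livers were 7.6 and 18.5 for igfbp1, 5.79 and 2.89 for igf1, 5.11 and 6.27 for scd, 9.27 and 5.76 for pparg, 31 and 21 for slc2a2, and 2.34 and 2.09 for cyp3a4. The lipogenic genes srebf1 (2.88 and 2), fasn (1.06 and 0.581) and acaca (0.782 and 0.718) were low in both groups. The genes pck1, insr, cpt1a, cyp7a1, ppara and thrb were too low to test, and vtgb1 and dio1 were not found under those symbols.

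Direct comparison showed where the exposures differed from each other. In mixture livers nfix (ENSXETG00000016718), a CCAAT-binding transcription factor, and jarid2 (ENSXETG00000015433, scaffold GL172669.1, 2967252 to 3028532), a cofactor of the Polycomb complex that deposits H3K27me3, were higher than in benzo[a]pyrene livers. Jarid2 stood at 35.8 ± 5.48 in mixture, 40.1 ± 13 in triclosan, 16.9 ± 3.43 in unexposed and 4.33 ± 6.84 in benzo[a]pyrene livers, a mixture minus benzo[a]pyrene log2 change of 3.52 (SE 0.54, adjusted p = 0.0183). Nfix stood at 2.06 ± 0.291 in mixture and 0.345 ± 0.22 in benzo[a]pyrene livers (log2 change 1.19, SE 0.17, adjusted p = 0.00925). Kdm6b (-1.23, adjusted p = 0.0183), XB-GENE-5857146 (-1.54, adjusted p = 0.00925) and msl1 (-1.51, SE 0.25, adjusted p = 0.0289) were lower in mixture livers. In each of these 5 genes, all 4 mixture libraries lay on one side of all 4 benzo[a]pyrene libraries. Nfix, kdm6b and XB-GENE-5857146 lie outside the naming rule and were chosen after their values were seen. The test called these 5 genes, with 908 genes below an unadjusted p of 0.05, and called 0 with the replicate number as a block. Leaving out benzo[a]pyrene replicates 1, 2, 3 or 4 gave 1, 2, 27 or 0 genes, and leaving out mixture replicates 1, 2, 3 or 4 gave 1, 3, 9 or 2.

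Benzo[a]pyrene and triclosan livers differed in the same 5 genes and in hpgd. Both comparisons use the same benzo[a]pyrene libraries, so their agreement is not independent support. Hpgd stood at 20 ± 11.2 in benzo[a]pyrene and 3.51 ± 0.846 in triclosan livers (log2 change 2.11, SE 0.31, adjusted p = 0.0149). Relative to triclosan, benzo[a]pyrene livers were higher in XB-GENE-5857146 (1.22, adjusted p = 0.0303), kdm6b (1.18, adjusted p = 0.027) and msl1 (1.42, adjusted p = 0.0443), and lower in jarid2 (-3.63, adjusted p = 0.0149) and nfix (-1.19, adjusted p = 0.0149). In each of these 6 genes the libraries of the groups did not overlap. At an unadjusted p of 0.05 there were 960 genes, and with the replicate number as a block 0 were called. Other splits of the same libraries gave 1151, 1033 and 980 genes at that p. Leaving out benzo[a]pyrene replicates 2, 3 or 4 gave 2, 58 or 0 genes, and leaving out triclosan replicates 1, 2 or 4 gave 1, 1 or 9.

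Mixture and triclosan livers differed in no gene past the test (limma, smallest adjusted p = 0.998), with 200 genes below an unadjusted p of 0.05 and 2.5% of genes without overlap. Nfix and jarid2 means in these groups were 2.06 and 2.1, and 35.8 and 40.1. No gene departed from the sum of the single-exposure changes (limma, smallest adjusted p = 0.197), with 488 genes below an unadjusted p of 0.05 and a median SE of 0.34. Leaving out benzo[a]pyrene replicate 3 gave 2 genes, and leaving out mixture replicate 3 gave 1.

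Log2 changes against the shared unexposed libraries were correlated across 6913 genes, which are not independent replicates. Pearson's r was 0.40 for benzo[a]pyrene and triclosan, 0.44 for benzo[a]pyrene and the mixture, and 0.58 for triclosan and the mixture, with Spearman's rho of 0.37, 0.43 and 0.59. Simulations in which the unexposed libraries alone linked the comparisons gave a mean r of 0.50 (0.44 to 0.55). Their noise was independent between genes, whereas real genes vary together. The range is therefore too narrow to judge the observed correlations by. With separate unexposed libraries for each exposure, the median r was 0.03, 0.08 and 0.14. Genes with an unadjusted p below 0.05 that were higher after both triclosan and the mixture numbered 54, against 4.8 by independence, a count that the shared libraries also raise.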

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

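The tests of a lower hepatocyte share, of library covariates, of benzo[a]pyrene replicate 4, of the rescaling and of held-out unexposed libraries, and the contrast pooling groups by compound, were chosen only after the results they concern had been seen. Chance flags about 1 in 20 groups of 4 as holding a library far from the others, which over 353 groups would give 17.7, and 32 were found.

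The first pattern was the shift of erythroid markers up (median log2 change 0.94, with a score of -0.05 in replicate 3 against 0.78 to 1.26 in the others) and of hepatocyte (-0.46) and ER chaperone genes (-0.88) down in benzo[a]pyrene livers. With the rRNA and mitochondrial shares as covariates, the ER chaperone median was -0.75 (camera adjusted p = 6.51e-07) and the erythroid median 1.08. The shares as measured therefore did not account for the whole of these shifts. The hepatocyte median shrank to -0.29 (camera adjusted p = 0.000676), so the shares may account for part of that list's shift. These p-values use the preset correlation, and without covariates an estimated correlation gave the ER chaperone list an adjusted p = 0.32. The mitochondrial share also lacks COX1 in benzo[a]pyrene replicates 3 and 4, so the covariates may correct too little. A lower share of hepatocytes as the whole cause would raise all other cell types. Bile duct members instead lay below 0 (median -0.64, quartiles -0.78 to -0.31) and erythroid ones above it (0.59 to 1.24). The erythroid minus bile duct score was 1.02 ± 0.59 in benzo[a]pyrene and -0.58 ± 0.25 in unexposed livers (exact p = 0.0286, adjusted p = 0.1 over 7 lists). Bile duct gave the smallest exact p of the 7 lists and was singled out after both shifts had been seen. Against the mean of the 7 lists the exact p was 0.0571, so the tests do not decide. More blood RNA in the samples may lower the other lists, but the ER chaperone score did not clearly follow the erythroid score within groups (16 libraries, r = -0.14, permutation p = 0.55, rho = -0.19, permutation p = 0.494, r = -0.19 without the 2 farthest libraries), so this stays open. A response of liver or blood cells to benzo[a]pyrene also stays open and was not tested apart from these.

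The second pattern was the set of 6 genes that set benzo[a]pyrene livers apart. The mixture minus benzo[a]pyrene log2 changes were -1.54 for XB-GENE-5857146, 3.52 for jarid2, 1.19 for nfix, -1.51 for msl1 and -1.23 for kdm6b, and the benzo[a]pyrene minus triclosan changes were 1.22, -3.63, -1.19, 1.42 and 1.18 for the same genes and 2.11 for hpgd. Replicate 4 of benzo[a]pyrene was the library of that group with the most rRNA. The median size of the mixture difference over the 6 genes was 1.46 without it and 1.44 with it, so their size did not rest on it alone. The genes had been picked from these same libraries, which left little room for another outcome. With 3 libraries no gene passed (limma, adjusted p from 0.0575 upwards). Without the rescaling the median size was 1.54, but nfix, msl1 and kdm6b then missed the threshold against the mixture (limma, adjusted p = 0.148, 0.194 and 0.1). The rescaling moved the median gene of this comparison only from -0.133 to -0.026. It could hardly have changed a difference of this size, so the test adds little. An exposure effect remains a hypothesis, and a difference in handling or sampling between groups cannot be excluded, because the labels name no batches.

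The third pattern was benzo[a]pyrene replicate 3, without which 46 genes were called against unexposed livers (35 higher and 11 lower). A candidate explanation is a mislabelled unexposed library. On a scale from 0 (unexposed mean) to 1 (mean of the other benzo[a]pyrene libraries), its median position over these genes was 0.36 (quartiles 0.12 to 0.51), nearer benzo[a]pyrene in 12 of 46 genes. This lay between the limits set beforehand for and against a mislabelled library, so it did not decide. Over 4 sets of 46 genes chosen without replicate 3 and without 1 unexposed library in turn, replicate 3 lay at 0.36 on average. The held-out unexposed libraries lay at 0.10 ± 0.09 (-0.02 to 0.17). By this criterion, added afterwards, the values argue against an unexposed library in its place, though with only 4 libraries for reference. Only 5 to 11 genes of each set were called. Held-out unexposed libraries themselves lay beyond the other unexposed ones in 7 to 26 of 46 genes, against 28 to 35 for replicate 3. A weaker response, a mixed sample or an exchange with a library of another group was not tested.

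How often chance alone gives such results was examined by counting other splits of the same libraries. For the mixture against benzo[a]pyrene, the real split called 5 genes and the highest other 2. Thus 1 of 35 splits gave as many, which is the smallest share possible. This share was not adjusted over the comparisons and does not by itself exclude chance. By genes at an unadjusted p of 0.05 the real split gave 908, and 3 other splits gave 1493, 1234 and 1017. For the other gene counts chance could not be excluded either. Benzo[a]pyrene against unexposed gave 2 genes (highest other 13, with 3 of 35 splits as many). Benzo[a]pyrene against triclosan gave 6 (highest other 24, with 2 of 35), and the pooled triclosan-or-mixture contrast 1 (highest other 60, with 13 of 100). For counts of 0 this test says nothing, since any split gives at least 0: triclosan (highest other 1; 35 of 35), mixture (2; 35 of 35), mixture against triclosan (1; 35 of 35) and additivity (3; 100 of 100). The split that gave 13 genes joined unexposed replicates 1 and 4 with benzo[a]pyrene replicates 3 and 4, the 4 libraries of highest rRNA share among the 8. This split was picked after the counts had been seen, and whether rRNA share accounts for its genes was not tested. For gene lists chance could not be excluded either: benzo[a]pyrene gave 17 (highest other 20; 2 of 35), triclosan 4 (17; 31 of 35) and the mixture 4 (15; 26 of 35).

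Among library measures, unexposed replicate 2 had 11.4 M implied fragments where the others of its group had 13.2 to 13.5. Mixture replicate 4 had an rRNA share of 10.59% against 1.14 to 2.3%, and a ribosomal protein share of 34.3% against 50.4 to 52%. The scale factor of triclosan replicate 4 was 1.12 against 0.95 to 0.97. Among list scores, unexposed replicate 4 was at -0.23 for insulin signalling (others 0.12 to 0.16), unexposed replicate 2 at -0.24 for vitellogenesis (0.02 to 0.07) and unexposed replicate 3 at -0.11 for macrophages (0.25 to 0.29). Benzo[a]pyrene replicate 4 was at -0.58 for lipoproteins (-0.15 to -0.07) and at -0.97 for ER chaperones (-0.42 to -0.32). Benzo[a]pyrene replicate 1 was at 0.19 for bile duct markers (-0.53 to -0.43), and mixture replicate 3 at -0.13 for steroid metabolism (0.1 to 0.13).

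Among genes in unexposed livers, replicate 4 stood apart in cenpk (0.277, others 0.676 to 0.681) and sult6b1 (1.51, others 2.82 to 3). Replicate 3 stood apart in ccdc69 (2.13, others 2.09), c14orf166 (4.01, others 1.16 to 1.28) and Vault (0, others 30.5 to 38.9), and replicate 2 in esr1 (1.04, others 1.8 to 1.93) and NFKBIZ (4.04, others 2.59 to 2.73). Benzo[a]pyrene replicate 1 stood apart in fasn (1.96, others 0.0587 to 0.222), acaca (1.95, others 0.25 to 0.352) and uchl3 (4.87, others 6.69 to 7.08). Benzo[a]pyrene replicate 2 stood apart in hpgd (36.7, others 13.3 to 15.3) and nfix (0.674, others 0.204 to 0.266), replicate 3 in Vault (24.6, others 0) and replicate 4 in cxxc1 (8.31, others 5.94 to 6.25). Triclosan replicate 1 stood apart in hpgd (2.27, others 3.8 to 4.17), scd (0.915, others 3.76 to 4.32), igf1 (7.16, others 2.26 to 2.73) and uchl3 (3.16, others 5.2 to 5.69). Triclosan replicate 2 stood apart in U1 (6.26, others 0), triclosan replicate 4 in vtga2 (174, others 2660 to 3990) and mixture replicate 4 in nfix (1.63, others 2.17 to 2.27). In the status column, which the comparisons did not use as a measurement, the globin hba1 was over the fragment limit of Cufflinks in 10 of 12 exposed and 1 of 4 unexposed libraries.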

How the results depend on the processing

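The fits without the libraries of high rRNA share (benzo[a]pyrene and mixture replicates 4) and with rRNA and mitochondrial shares as covariates, and the left-out libraries for the share of the 10 most abundant genes, were chosen only after the data had been seen. No called gene or list changed direction among the 1305 alternative values for genes and 271 for lists that were compared. Gene values were compared for FPKM as deposited, other pseudocounts, the replicate block, left-out libraries and the fit without the high-rRNA libraries. Direction was not compared for genes under the other alternatives, nor for lists under alternatives in which lists were not tested. Of 187 gene results, 174 were not called, so, counting the lowest and highest of the left-out fits per result, most of the 1246 of 1305 alternative values that kept their side of the threshold were uncalled values that stayed so. All 52 losses fell on the 13 called results, and 7 uncalled results gained a call under 1 of these alternatives each. That count holds only the lowest and highest left-out fits. Without benzo[a]pyrene replicate 3, hpgd, nt5c3a, ttr, prodh2, impdh2, msl1, cenpk, susd1, ccdc69 and mllt10 were all called against unexposed livers. Of 271 such values for 25 called lists, 190 kept the call and 81 lost it. Over all 200 left-out fits of the 25 called lists, 32 lost the call, in 14 lists. Calls therefore rested on thin margins, and the FPKM scale limits what can be read from genes near 0. Where a count below moved, the cause was not tested unless fewer libraries or genes entered the fit.

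For benzo[a]pyrene minus unexposed (2 genes), 0 genes were called with FPKM as deposited, a pseudocount of 0.1, a filter at FPKM 5, the replicate block, only the groups compared, or without the 2 libraries of high rRNA share. No filter gave 1, library weights 7 and the covariates 5. For mixture minus benzo[a]pyrene (5 genes), FPKM as deposited gave 3, the filter at FPKM 5 gave 2, and the replicate block, only the groups compared and the fit without the high-rRNA libraries gave 0. For benzo[a]pyrene minus triclosan (6 genes), FPKM as deposited gave 2, a pseudocount of 0.1 gave 3, a pseudocount of 5 gave 25, the filter at FPKM 5 gave 19, only the groups compared 1, library weights 61, limma without the robust option 11 and the covariates 22. The replicate block and the fit without the high-rRNA libraries gave 0. From 0 genes, the covariates gave 2 for triclosan, only the groups compared gave 1 for the mixture and 1 for mixture minus triclosan, and no filter gave 1 for additivity. The replicate block assumes that equal numbers mark paired samples, which the data did not bear out: over 24 pairs of the same number the median correlation of residuals was -0.05 (-0.25 to 0.26), and 4 of 16 libraries matched best within their number.

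Called lists fell to 0 with an estimated correlation in all 3 exposures, and with fry to 2 for benzo[a]pyrene (from 17) and 0 for triclosan and the mixture (from 4 each). The filter at FPKM 5 gave 1 for triclosan and 2 for the mixture. Leaving out the high-rRNA libraries gave 2 and 7, and the covariates gave 7 for the mixture. Of the 25 called lists over all exposures, the filter at FPKM 5 lost 9, the covariates 6 and leaving out the high-rRNA libraries 4. With separate unexposed libraries, the correlation of changes fell to a median of 0.03 (-0.06 to 0.11) for benzo[a]pyrene and triclosan, 0.08 (0.01 to 0.13) for benzo[a]pyrene and the mixture, and 0.14 (-0.02 to 0.22) for triclosan and the mixture, which removes the shared libraries but leaves 2 per comparison.

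Leaving out each library in turn gave 0 to 46 genes for benzo[a]pyrene (0 without each unexposed library, 46 without benzo[a]pyrene replicate 3), 0 to 27 for mixture minus benzo[a]pyrene (0 without benzo[a]pyrene replicate 4, 27 without replicate 3), 0 to 58 for benzo[a]pyrene minus triclosan (the same libraries) and 0 to 2 for additivity. Triclosan, the mixture and mixture minus triclosan stayed at 0. Lists ranged from 15 to 19 for benzo[a]pyrene, 1 to 7 for triclosan (without unexposed replicates 1 and 4) and 2 to 10 for the mixture (without mixture replicate 3 and unexposed replicate 4). The share of the 10 most abundant genes moved from -2.81 to 1.83 percentage points for benzo[a]pyrene, -3.41 to 0.76 for triclosan and -0.37 to 4.9 for the mixture. Quantile normalization gave 2, 5 and 8 genes in the 3 comparisons with calls.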

Other observations

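The contrasts that pool groups by compound, the list scores with exact tests and the genes named here outside the naming rule were chosen only after the results had been seen. The relation of jarid2 to the clock score and the ERK feedback genes were tests of patterns noticed in the data.

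Livers exposed to triclosan or the mixture (8 libraries), compared with unexposed or benzo[a]pyrene livers (8 libraries), had 1 gene past the test: nfix at 2.08 ± 0.562 and 0.811 ± 0.531 (SD, n = 8, log2 change 0.81, SE 0.12, limma adjusted p = 0.0328). It was not called in 10 of the 16 fits that left out 1 library, including each that left out an unexposed one. The Polycomb cofactor jarid2 (adjusted p = 0.0636) stood at 38 and 10.6 in the same pools, and the organic anion and cyclic nucleotide transporter abcc5 (adjusted p = 0.11) at 19.9 and 8.86. The comparison pool includes benzo[a]pyrene livers, with nfix at 0.204 to 0.674 and jarid2 at 4.33, against 16.9 for jarid2 in unexposed livers. The pooled differences are therefore not differences from unexposed livers alone, against which neither triclosan nor the mixture had a called gene. At an unadjusted p of 0.05 there were 723 genes. Without benzo[a]pyrene replicate 3 there were 6 called genes and without triclosan replicate 3 there were 3.

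Livers exposed to benzo[a]pyrene or the mixture, compared with unexposed or triclosan livers, had no gene past the test (limma, smallest adjusted p = 0.134, with 677 genes at an unadjusted p of 0.05), but 4 without benzo[a]pyrene replicate 3 and 1 without benzo[a]pyrene replicate 2. Transthyretin stood at 140 ± 76 and 351 ± 125 (SD, n = 8), prodh2 at 7.38 and 14.6, the IGF-binding protein igfbp2 at 9.57 and 20.8, and nmrk2, a kinase of the NAD salvage pathway, at 71.2 and 27.5. Bile duct markers were shifted lower in these pools (camera adjusted p = 8.72e-05, and adjusted p = 0.0663 with an estimated correlation). By list scores, bile duct markers were lower in all 4 mixture libraries than in any unexposed one (exact p = 0.0286, adjusted p = 0.648). In benzo[a]pyrene livers, erythroid, bile acid, steroid and circadian clock scores did not overlap with unexposed ones (exact p = 0.0286 each, adjusted p = 0.243).

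In 3 of 4 benzo[a]pyrene libraries jarid2 was at 0.413 to 1.33, and the histone demethylase kdm7a (ENSXETG00000002669) at 0.234 to 9.6, while replicate 3 had 14.6 and 157. Unexposed livers averaged 16.9 ± 3.43 and 75.7 ± 26.9. The pair was picked for this shared pattern, so a correlation between them would restate it. The hypothesis that both follow a difference in clock phase or time of sampling was tested with the circadian clock score, which gave r = -0.29 with jarid2 (permutation p = 0.433, adjusted p = 0.433 over 2 relations computed, rho = -0.08, permutation p = 0.789, r = 0.38 without the 2 farthest libraries). The sign of the relation rested on those 2 libraries. The score is also a plain mean over clock genes that did not vary together (estimated correlation -0.03). A phase shift that raised some and lowered others would cancel out in it, so the hypothesis stays open.

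The genes dusp6, spred1 and etv1, which are induced by ERK signalling and in part restrain it, had negative changes after each exposure: -0.64, -0.50 and -0.34 after benzo[a]pyrene, -0.46, -0.61 and -0.56 after triclosan, and -0.55, -0.86 and -0.67 after the mixture. None passed over all genes. These changes share the unexposed libraries and are not independent. Lower ERK feedback transcription in exposed livers may account for them, and it was tested on the other 6 tested genes of 16 fixed for this purpose (spred2, spry2, egr1, fos, myc and IER2). Their mean score differed by -0.18 between 12 exposed and 4 unexposed libraries (exact p = 0.505), which does not decide.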
